A study of Homo sapiens with 6 samples.

How the data were processed

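Total RNA of 6 samples was measured on Illumina HumanRef-8 v3 bead arrays: 2 arrays each of HUES9 hESC, pNSC at passage 6 and pNSC at passage 27. Per the labels, the pNSC medium held LIF at 10 ng/ml, CHIR99021 at 3 µM, SB431542 at 2 µM and bovine serum albumin at 5 µg/ml. The labels of the HUES9 arrays repeat that description, so the medium of the hESC is not known. The deposited values are intensities on a linear scale, 1 per probe and array. BeadStudio is named in the submitters' processing notes, with its version and role not stated. The lowest intensities lay well above 0 and the quantiles of the arrays nearly coincided, so the deposited values carried background and had been put on a common scale before deposit. A further deposited table held 12 value columns (intensities and detection p values) under names that match no sample, and was not used.

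The array median of the intensity lay between 90.2 and 94.8. Of 24526 probes, 21834 carried 1 gene symbol, 21813 of them matched to a current symbol through their Entrez gene ID, and 2692 had no symbol and were left out of the gene tests. The plan had been to correct background and normalize with neqc, using an offset of 16, and to keep probes with a detection p under 0.01 in both arrays of at least 1 group. Since no detection p could be given to a sample, a different procedure was used, chosen after the format of the values was seen and before any comparison was run. Background was corrected with normexp at an offset of 50, followed by quantile normalization and log2 (limma 3.58.1 in R 4.3.3). Probes were kept if their deposited intensity was at least 128 (7 on the log2 scale) in both arrays of at least 1 group. The values of 491 probes of presumed silent genes (olfactory and taste receptors, keratin-associated proteins and beta-defensins) had a median intensity of 56. Over all 6 arrays, 1.93% of these values reached that minimum. In all 11146 probes were kept, 917 of them without a symbol. Each of 9054 genes was represented by its probe with the highest mean over all 6 arrays.

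A linear model with 1 mean per group was fitted to all 6 arrays with limma and its standard errors moderated with eBayes. The residual degrees of freedom were 3, and 10.54 with the prior. The median standard error of a log2 fold change was 0.17, and the median half-width of a 95% confidence interval 0.38. The 3 comparisons were passage 6 against hESC, passage 27 against hESC, and passage 27 against passage 6, each with Benjamini-Hochberg adjustment over the genes and a call at an adjusted p under 0.05. Tests were two-sided. Folds against a group with both arrays under the minimum are given as lower bounds with that group at the minimum.

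Of 37 gene lists written before the data were examined, 35 had at least 5 members measured and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. The genes named were a fixed set chosen beforehand, and called genes picked by the size of their change. These were the 8 with the highest and the 8 with the lowest fitted log2 fold change per comparison, and up to 4 per list. Left out of these picks were genes with placeholder symbols, such as those starting with LOC or KIAA, and others excluded beforehand. For the 8 and 8, both arrays of the group with the higher level had to reach the minimum. Any other named gene is said to have been picked after its values were seen. Genes of each of 22 autosomes were tested the same way between passages. The sharing of genes by the 2 comparisons with hESC was set against 100 simulations without effect in which the control arrays were shared.

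The procedure was tested on simulated data with known changes. At each fold 66 or 67 genes were changed, all at an intensity of at least 200 in the reference group. Recovery of genes nearer the minimum was therefore not tested. Noise was drawn independently for each probe, with no array standing apart. In the simulated comparison of passage 6 with hESC (8467 genes), 14.9% of 1.5-fold, 80.6% of 2-fold and 98.5% of 4-fold changes were recovered, with 4 false among 136 calls. For passage 27 against hESC (8482 genes) the shares were 22.4%, 80.6% and 98.5%, with 11 false among 149 calls. For passage 27 against passage 6 (8259 genes) they were 25.4%, 89.6% and 100%, with 9 false among 154 calls. Folds were underestimated: over the 3 comparisons the median estimate was 1.78 to 1.82 for 2-fold and 3.32 to 3.51 for 4-fold changes. In the data 10 genes differed by at least 1 on the log2 scale between passages, and 3 of them were called. With so few calls the adjusted threshold is stricter than in the simulation. The simulated shares therefore do not say how many 2-fold changes between passages would have been found. A simulated list of 20 genes shifted by 0.5 had a camera p between 1.37e-18 and 1.49e-18, and between 0.00238 and 0.00499 with an estimated correlation.

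The alternatives tried were no background correction, a smaller offset, median scaling, cyclic loess, the deposited values as they were, no filter, other minimums, the minimum in all 6 arrays, all probes of a gene or their mean, eBayes with trend and robust settings, only the 2 groups compared, the replicate number as a block, each array left out in turn, and treat against a 1.2-fold change.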

Results

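RNA was measured on 6 Illumina HumanRef-8 v3 bead arrays, on which each probe is carried by many beads and the deposited value is the probe's summarized intensity. The arrays held 3 groups of 2: HUES9, an established line of human embryonic stem cells (hESC), and primitive neural stem cells (pNSC) at passage 6 and at passage 27. The pNSC were labelled as early neural precursors grown with leukemia inhibitory factor (LIF, a cytokine acting through STAT3), CHIR99021 (an inhibitor of GSK3, which activates WNT signalling) and SB431542 (an inhibitor of the TGF-beta and Activin receptors). The median intensity of an array lay between 90.2 and 94.8, and the summed intensity between 15988420 and 16563056. Of the probes, 41.17% to 42.08% per array reached the minimum intensity of 128, and 9054 genes were tested with limma. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.17. The labels do not say whether the duplicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

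The first comparison asked how pNSC at passage 6 differed from the hESC. Among genes that passed the minimum intensity, most pluripotency genes of hESC were lower in pNSC. Most genes of the neural stem cell, neuronal and HOX lists that passed it were higher. NANOG fell at least 28.9-fold (log2 fold change -5.98 ± 0.18, standard error, n = 2 arrays per group; limma adjusted p = 3.79e-09) and POU5F1 at least 16.6-fold (-5.24 ± 0.19; limma adjusted p = 7.75e-09). PAX6, a regulator of neural progenitors, rose at least 16.3-fold (5.27 ± 0.20; limma adjusted p = 1.24e-08), and the hindbrain gene HOXB2 rose at least 25.6-fold (5.63 ± 0.17; limma adjusted p = 3.79e-09). A fold given as "at least" is a lower bound, computed with the group whose arrays lay under the minimum intensity set to that minimum. Both POU5F1 and NANOG have near-identical pseudogene copies, whose share of the signal the probes cannot exclude.

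In this comparison 4695 of the 9054 genes were called at an adjusted p under 0.05, 2330 of them higher and 2365 lower in pNSC. Of the called genes, 2114 differed at least 2-fold, 991 higher and 1123 lower. Under the rule for naming genes, the 8 with the highest fitted log2 fold changes were led by NR2F1 (at least 35.6-fold, log2 6.37 ± 0.22). Then came the chemokine receptor gene ACKR3 (58.9-fold, 5.88 ± 0.25), HOXB2, IRX3 (48.7-fold, 5.61 ± 0.22), NCALD, CNTFR, HOXA2 and PAX6. CNTFR, which encodes a receptor subunit for a cytokine of the LIF family, rose at least 33.9-fold (5.52 ± 0.16). The 8 with the lowest were ACTA1 (at least 137-fold, log2 -7.60 ± 0.17), GAL (at least 77.0-fold, -7.22 ± 0.22), L1TD1 (at least 78.6-fold, -6.76 ± 0.16), ZFP42 (at least 46.8-fold, -6.58 ± 0.17), RAB17, GRPR, CRIPTO and NANOG. The order is not settled where a fold is a bound, since genes with smaller fitted values, such as HES4 (26.9-fold) and DLL1 (24.9-fold), have folds above the bounds of PAX6 and HOXA2, with all their arrays over the minimum.

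Among the genes chosen before the data were examined, the epithelial adhesion genes CDH1 and EPCAM fell at least 26.6-fold (log2 -5.82 ± 0.19) and 13.2-fold (-3.73 ± 0.19), and CDH2, the cadherin of neural epithelium, rose 1.92-fold (0.94 ± 0.18; limma adjusted p = 0.00105). DNMT3B fell 10.8-fold (-3.44 ± 0.27), LEFTY2 at least 18.5-fold (-5.10 ± 0.22), and LIN28A 2.00-fold (-1.0 ± 0.17; limma adjusted p = 0.000527). SOX2, which marks both pluripotent and neural stem cells, was not called (0.20 ± 0.18; limma adjusted p = 0.393), and its sign turned without passage 6 replicate 1 (-0.01). NES rose 3.50-fold (1.81 ± 0.18) and ZBTB16, a marker of neural rosettes, at least 8.74-fold (4.21 ± 0.27). The forebrain and midbrain gene OTX2 fell at least 14.9-fold (-4.73 ± 0.19), and GBX2, expressed behind the midbrain, rose at least 3.48-fold (2.20 ± 0.22). AXIN2, a target of WNT signalling, rose 2.12-fold (1.09 ± 0.19; limma adjusted p = 0.000781). SOX1, EN1 and LMX1B stayed under the minimum in all 6 arrays, with intensities of 48.4 to 61 for SOX1, 67.4 to 86.9 for EN1 and 63.0 to 72.5 for LMX1B, and HES5 had no probe with its name.

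**Figure D1:**
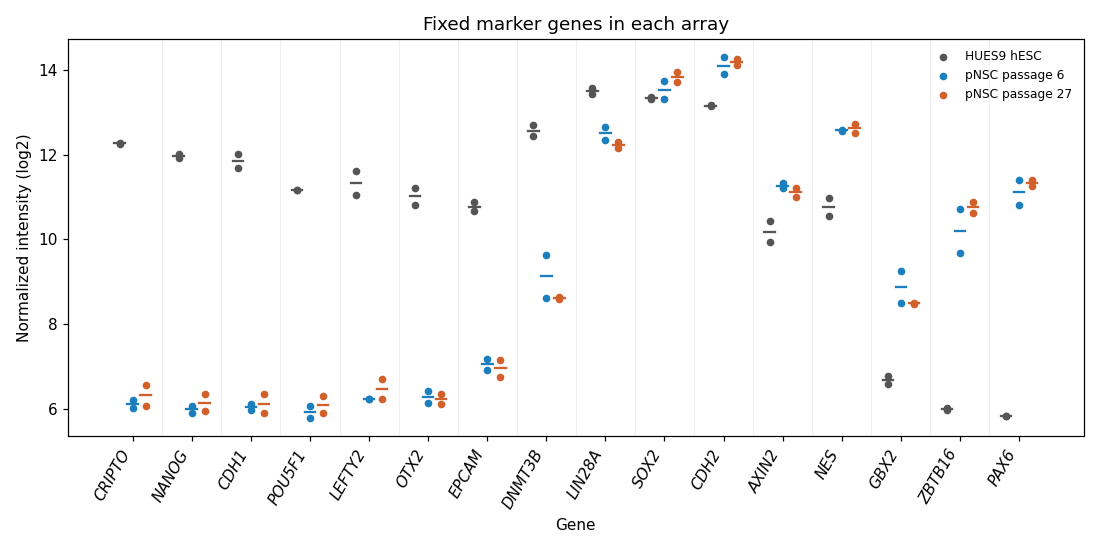
Normalized log2 intensity of 16 genes in each of the 6 arrays, with a bar at the mean of the 2 arrays of a group; genes are ordered by the difference between pNSC passage 6 and HUES9 hESC. POU5F1 and NANOG lie low in all 4 pNSC arrays, where PAX6 and ZBTB16 lie high, and values near 6 are at the background of the array.

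Lists of genes fixed beforehand were tested as sets with camera, which compares a list with all other genes. Only members over the minimum in both arrays of at least 1 group were counted. Of the genes on the array these were 30 of 35 pluripotency, 27 of 37 neural stem cell and 20 of 38 neuronal genes. They were also 12 of 29 HOX, 11 of 27 mid-hindbrain and 7 of 27 forebrain genes. A member dim in hESC passed only through pNSC, which favours rises, and a member dim in pNSC only through hESC, which favours falls. Of the 35 lists with enough members, 13 were called at passage 6. None was called when the correlation between members was estimated from the arrays (lowest adjusted p = 0.292), so each call below rests on the preset correlation.

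Of 30 pluripotency genes, 28 fell, 0 rose and 2 were not called, with 28 falling when adjusted over the list alone (camera adjusted p = 2.36e-15; adjusted p = 0.292 with an estimated correlation). CRIPTO, the Nodal co-receptor, fell at least 35.5-fold (log2 -6.16 ± 0.19), beside GAL, L1TD1 and ZFP42. Of 22 target genes of TGF-beta and Activin signalling, 18 fell, 1 rose and 3 were not called, with the same counts of 18 and 1 adjusted over the list alone (camera adjusted p = 4.7e-08; adjusted p = 0.401 with an estimated correlation). Of its measured genes 6, with CRIPTO, NANOG, LEFTY1 and LEFTY2 among them, are also in the pluripotency list, and LEFTY1 fell at least 25.9-fold (-5.80 ± 0.18). Of 9 epidermal and trophoblast genes, 8 fell, 0 rose and 1 was not called, with 8 falling adjusted over the list alone (camera adjusted p = 6.52e-07; adjusted p = 0.376 with an estimated correlation). EPHA1 fell at least 21.3-fold (-5.44 ± 0.18), KRT19 at least 8.31-fold (-4.12 ± 0.19) and OVOL2 at least 8.63-fold (-4.21 ± 0.19).

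Of 27 neural stem cell genes, 21 rose, 2 fell and 4 were not called, with 22 rising and 2 falling adjusted over the list alone (camera adjusted p = 1.07e-07; adjusted p = 0.292 with an estimated correlation). Besides NR2F1 and PAX6, SOX21 rose 17.1-fold (log2 4.09 ± 0.17) and POU3F2 at least 12.8-fold (4.31 ± 0.23). Of 13 genes of neural rosettes, the radial epithelia of early neural culture, 10 rose, 1 fell and 2 were not called, with 10 and 1 adjusted over the list alone (camera adjusted p = 6.96e-05; adjusted p = 0.376 with an estimated correlation). PLAGL1 rose at least 16.6-fold (4.77 ± 0.30), and NNAT was the 1 that fell, at least 19.5-fold (-5.05 ± 0.15). Of 20 neuronal genes, 14 rose, 1 fell and 5 were not called, with 14 and 1 adjusted over the list alone (camera adjusted p = 3.5e-05; adjusted p = 0.376 with an estimated correlation). NEFM rose 20.4-fold (4.35 ± 0.18), STMN2 17.7-fold (4.14 ± 0.26) and DCX 15.2-fold (3.93 ± 0.18). Of 11 glial genes, 9 fell, 1 rose and 1 was not called, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.000553; adjusted p = 0.376 with an estimated correlation). APOE fell at least 18.4-fold (-4.91 ± 0.19) and GJA1 10.8-fold (-3.43 ± 0.16), whereas the glutamate transporter gene SLC1A3, also active in radial glia, rose 6.5-fold (2.70 ± 0.17).

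Of 12 HOX genes of the hindbrain and spinal cord, 10 rose, 1 fell and 1 was not called, with 10 and 1 adjusted over the list alone (camera adjusted p = 5.89e-05; adjusted p = 0.401 with an estimated correlation). HOXA2 rose at least 17.4-fold (log2 5.34 ± 0.18), HOXB8 at least 6.55-fold (3.54 ± 0.18) and HOXC4 at least 2.89-fold (2.60 ± 0.16). Of the 7 forebrain genes that passed the minimum, out of 27 on the array, 3 rose and 4 fell, with 3 and 4 adjusted over the list alone. The list was not called (camera adjusted p = 0.787, and 0.941 with an estimated correlation). SP8 rose at least 3.17-fold (2.11 ± 0.17), and HESX1 fell at least 2.41-fold (-2.12 ± 0.21). Of 11 genes of the midbrain and hindbrain 4 rose, 5 fell and 2 were not called, with 4 and 5 adjusted over the list alone, and that list was not called either (camera adjusted p = 0.988; adjusted p = 0.993 with an estimated correlation). IRX5 rose at least 21.3-fold (5.07 ± 0.27), as IRX3 did, while SPRY1 fell at least 13.6-fold (-4.47 ± 0.17).

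Of 20 Notch genes, 13 rose, 5 fell and 2 were not called, with 13 and 5 adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.517 with an estimated correlation). The ligand gene DLL1 rose 24.9-fold (log2 4.64 ± 0.18) and HES4 26.9-fold (4.75 ± 0.16), while HEY2 fell at least 11.5-fold (-4.36 ± 0.22). Of 9 Hedgehog genes, 7 rose, 0 fell and 2 were not called, with 8 rising adjusted over the list alone (camera adjusted p = 0.000553; adjusted p = 0.292 with an estimated correlation). GAS1 rose 28.8-fold (4.85 ± 0.21) and BOC at least 4.82-fold (3.47 ± 0.22). The lists of WNT targets (7 rose, 6 fell, 3 not called), BMP targets (7, 7 and 1), FGF genes (6, 11 and 2) and LIF and STAT3 genes (3, 7 and 5) had the same counts of rises and falls adjusted over the list alone, and were not called by camera. Their camera adjusted p values were 0.723, 0.787, 0.122 and 0.224, and with an estimated correlation the adjusted p values were 0.795, 0.941, 0.652 and 0.569. Among WNT targets LEF1 rose at least 9.56-fold (3.75 ± 0.15) and MYC fell 13.0-fold (-3.70 ± 0.17). Among BMP targets MSX1 rose at least 7.31-fold (3.63 ± 0.21) and BAMBI fell 26.5-fold (-4.73 ± 0.15). In the FGF list SPRY4 fell 8.23-fold (-3.04 ± 0.17), and in the LIF and STAT3 list SOCS1 fell at least 4.93-fold (-3.13 ± 0.20) and PIM1 5.50-fold (-2.46 ± 0.17).

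Of 19 genes of cholesterol synthesis, 13 rose, 0 fell and 6 were not called, with 13 rising adjusted over the list alone (camera adjusted p = 0.00202; adjusted p = 0.292 with an estimated correlation). TM7SF2 rose 2.64-fold (log2 1.40 ± 0.19) and HMGCS1 2.62-fold (1.39 ± 0.18). Of 20 genes of p53 signalling and cell-cycle arrest, 11 rose, 1 fell and 8 were not called, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.00761; adjusted p = 0.376 with an estimated correlation). CDKN1A rose 6.89-fold (2.78 ± 0.29) and CDKN1C 4.83-fold (2.27 ± 0.20). Of 17 genes of antigen presentation and interferon response, 8 fell, 3 rose and 6 were not called, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.0382; adjusted p = 0.529 with an estimated correlation). IFITM1 fell 26.5-fold (-4.73 ± 0.19) and TAP1 at least 4.99-fold (-3.34 ± 0.17).

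The second comparison set pNSC at passage 27 against the hESC, to ask whether the difference was there after long culture. Among genes that passed the minimum intensity, most pluripotency genes were again lower, and most genes of the neural stem cell, neuronal and HOX lists higher. NANOG fell at least 28.7-fold (log2 -5.82 ± 0.18, n = 2 arrays per group; limma adjusted p = 5.11e-09), and POU5F1 at least 16.5-fold (-5.07 ± 0.19; limma adjusted p = 1.03e-08). PAX6 rose at least 19.1-fold (5.49 ± 0.20; limma adjusted p = 1.03e-08) and NR2F1 at least 42.4-fold (6.62 ± 0.22; limma adjusted p = 5.9e-09). The low intensities of NANOG and POU5F1 differed between the duplicates, at 51.4 and 72.1 for NANOG and 49.5 and 70.0 for POU5F1, all under the minimum.

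At passage 27, 4556 genes were called, 2332 higher and 2224 lower, and 2046 of them differed at least 2-fold, 1037 higher and 1009 lower. ACKR3 rose 69.5-fold (log2 6.12 ± 0.25), IRX3 54.4-fold (5.76 ± 0.22) and NCALD at least 36.9-fold (5.64 ± 0.16). ACTA1 fell at least 136-fold (-7.59 ± 0.17), GAL at least 76.6-fold (-7.07 ± 0.22) and L1TD1 at least 78.2-fold (-6.65 ± 0.16). DNMT3B fell 15.5-fold (-3.95 ± 0.27), LIN28A 2.42-fold (-1.28 ± 0.17) and OTX2 at least 14.8-fold (-4.79 ± 0.19). ZBTB16 rose at least 12.8-fold (4.76 ± 0.27), NES 3.61-fold (1.85 ± 0.18), GBX2 at least 2.66-fold (1.81 ± 0.22) and AXIN2 1.91-fold (0.93 ± 0.19; limma adjusted p = 0.00218). SOX2 rose 1.43-fold (0.51 ± 0.18; limma adjusted p = 0.0367). With 1 array of either group left out, which leaves that group a single array and the spread to the others, SOX2 was not called. Its log2 fold change was 0.63 without passage 27 replicate 1 (adjusted p = 0.0759), 0.39 without replicate 2 (0.27), 0.49 without HUES9 replicate 1 (0.121) and 0.53 without HUES9 replicate 2 (0.101). At the unchanged 0.51 the call of SOX2 also ended with a smaller offset (adjusted p = 0.0547), with no filter on dim probes (0.0519) and against a 1.2-fold minimum change (0.214).

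The lists called at passage 27 were 12 of the 13 called at passage 6, and again none was called with an estimated correlation. Of the pluripotency genes 27 fell, 1 (SOX2) rose and 2 were not called, with 28 and 1 adjusted over the list alone (camera adjusted p = 6.07e-16; adjusted p = 0.283 with an estimated correlation). Of the neural stem cell genes 21 rose, 2 fell and 4 were not called, with 21 and 2 adjusted over the list alone (camera adjusted p = 7.95e-08; adjusted p = 0.283 with an estimated correlation), and SOX21 rose 21-fold (log2 4.39 ± 0.17). Of the HOX genes 10 rose, 1 fell and 1 was not called, with 10 and 1 adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.351 with an estimated correlation), and HOXB8 rose at least 10.7-fold (4.26 ± 0.18). Of the neuronal genes 14 rose, 2 fell and 4 were not called, with 15 and 2 adjusted over the list alone (camera adjusted p = 4.74e-06; adjusted p = 0.351 with an estimated correlation), and STMN2 rose 17.6-fold (4.14 ± 0.26). Of the cholesterol synthesis genes 15 rose, 0 fell and 4 were not called, with 15 rising adjusted over the list alone (camera adjusted p = 0.000441; adjusted p = 0.283 with an estimated correlation), and HMGCS1 rose 3.06-fold (1.62 ± 0.18).

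The other lists called at passage 27 kept their direction. The TGF-beta and Activin targets had 1 rise and 18 falls (camera adjusted p = 2.42e-08), with 19 falls adjusted over the list alone, and LEFTY1 fell at least 25.7-fold (log2 -5.69 ± 0.18). The epidermal and trophoblast genes had 8 falls and 0 rises (7.27e-07), and EPHA1 fell at least 21.2-fold (-5.36 ± 0.18). The rosette genes had 9 rises and 2 falls (0.000123), the glial genes 1 and 9 (0.00106), the Notch genes 12 and 5 (0.0128), the Hedgehog genes 7 and 0 (0.00109), and the p53 and arrest genes 11 and 1 (0.0105). Adjusted over the list alone, the counts for these 6 lists were the same except that 8 Hedgehog genes rose. With an estimated correlation the adjusted p values of these 7 lists lay between 0.29 and 0.515. PLAGL1 rose at least 23.8-fold (5.29 ± 0.30), DLL1 28.6-fold (4.84 ± 0.18), GAS1 34.9-fold (5.13 ± 0.21) and CDKN1A 7.68-fold (2.94 ± 0.29). Of the antigen presentation and interferon genes 7 fell and 3 rose, and the list was no longer called (camera adjusted p = 0.118; adjusted p = 0.651 with an estimated correlation).

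**Figure D2:**
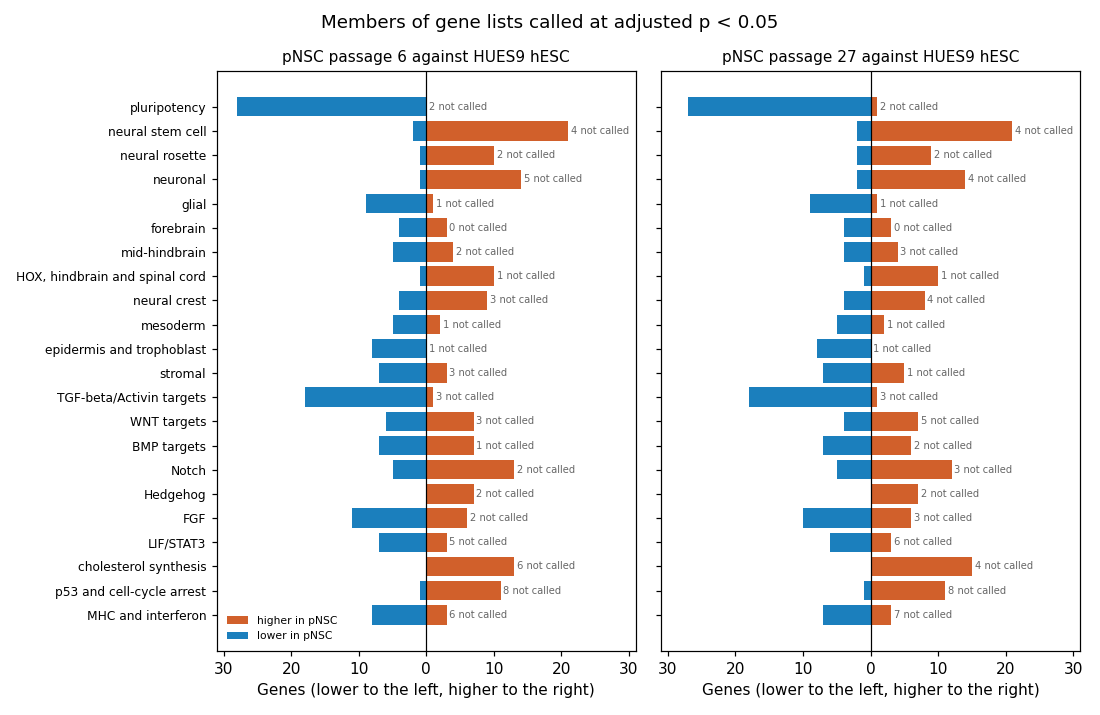
Number of genes of 22 lists called lower (left of 0) or higher (right of 0) in pNSC than in HUES9 hESC, at passage 6 and at passage 27, with the number not called printed beside each bar. Members that passed the minimum in no group are left out. The pluripotency genes lie almost wholly to the left and the neural stem cell genes mostly to the right at both passages.

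The 2 comparisons shared most of their genes. Called in the same direction at both passages were 2043 higher and 2032 lower genes, together 4075 of the 5176 called at either, with 0 in opposite directions. A further 620 were called at passage 6 alone and 481 at passage 27 alone. Lists of these sizes drawn independently would share 600.1 higher and 580.9 lower genes. Across the 9054 genes, which are not independent replicates, the log2 fold changes had r = 0.981 and a covariance of 1.17. Both comparisons used the same 2 hESC arrays, which alone gave a mean r of 0.50, a covariance of 0.0169, and means of 0.02 higher and 0.04 lower shared genes (at most 1) in 100 simulations without any effect. The hESC arrays were not divided between the comparisons, which would have left 1 for each, so part of the agreement may come from the shared controls.

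The third comparison set passage 27 directly against passage 6, to ask what changed in pNSC during prolonged culture. Only 3 genes were called, and all 3 were higher at passage 27. The collagen gene COL1A2 rose at least 1.89-fold (log2 1.88 ± 0.18, n = 2 arrays per group; limma adjusted p = 0.00577), and the imprinted gene NNAT at least 1.59-fold (1.43 ± 0.15; limma adjusted p = 0.00844). HOXC6, a HOX gene of the spinal cord, rose 2.33-fold (1.22 ± 0.16; limma adjusted p = 0.0463). COL1A2 and NNAT stayed below their hESC level at passage 27 (-2.84 and -3.62), and HOXC6 was under the minimum in both hESC arrays (intensities 91.5 and 95.9).

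At an unadjusted p under 0.05 the limma count was 313. Without any difference a share of 0.05 of the 9054 tested genes would pass, which is more than 313. In all 10 genes differed by at least 1 on the log2 scale. The count of called genes changed with the arrays used: it was 782 without passage 6 replicate 1, and 0 without passage 27 replicate 1 or without passage 27 replicate 2. Without passage 6 replicate 1, that group is replicate 2 alone, which stood apart from the other pNSC arrays. With a passage 27 array left out, the passage 27 group is likewise a single array and the other groups give the spread. The log2 fold changes of COL1A2, NNAT and HOXC6 were then 1.96, 1.45 and 1.17 without replicate 1 and 1.80, 1.41 and 1.26 without replicate 2, and none was called (adjusted p = 0.0753, 0.263 and 1.0, and 0.167, 0.343 and 0.596). HOXC6 was also not called without passage 6 replicate 2 (1.07, adjusted p = 0.0999) or without either HUES9 array (1.22, adjusted p = 0.0808). At the unchanged 1.22 the call of HOXC6 ended with no filter on dim probes (limma adjusted p = 0.136), with a minimum of 100 (0.0533) and with all kept probes tested (0.0914). It also ended against a 1.2-fold minimum change (0.193) and with only the 2 groups in the model (0.0808). The last is in effect the same fit as without either HUES9 array. The call of COL1A2 ended with no filter as well (1.88, adjusted p = 0.072). Between passages the median absolute log2 fold change was 0.13, against 0.48 and 0.47 for the 2 comparisons with hESC, and it was 0.25 without passage 6 replicate 1 and 0.09 without passage 6 replicate 2. Taken as single arrays, the 4 pairs across passages differed by medians of 0.084, 0.12, 0.243 and 0.261, the passage 6 duplicates by 0.247 and the passage 27 duplicates by 0.115, and the larger values are those of pairs with passage 6 replicate 2. None of the genes chosen beforehand was called between passages: ZBTB16 differed by 0.55 ± 0.27, DNMT3B by -0.51 ± 0.27, SOX2 by 0.31 ± 0.18 and PAX6 by 0.22 ± 0.20.

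Of the 35 lists, 4 were called by camera between passages, and none with an estimated correlation (lowest adjusted p = 0.725). Of 13 stromal genes, 1 (COL1A2) rose, 0 fell and 12 were not called, with 10 rising adjusted over the list alone (camera adjusted p = 6.41e-12; adjusted p = 0.725 with an estimated correlation). Among its members not called, picked after their values were seen, DCN differed by 1.14 ± 0.16 (limma adjusted p = 0.0507) and COL3A1 by 1.05 ± 0.16 (limma adjusted p = 0.0684). Of the 12 HOX genes, 1 (HOXC6) rose, 0 fell and 11 were not called, with 5 rising adjusted over the list alone (camera adjusted p = 1.69e-05; adjusted p = 0.801 with an estimated correlation). HOXB7 and HOXB8, also not called and picked after their values were seen, differed by 1.10 ± 0.26 and 0.71 ± 0.18. All 13 stromal genes and 91.7% of the HOX genes were lower in passage 6 replicate 2 than in the mean of the other 3 pNSC arrays, and without that array the 2 lists had camera adjusted p values of 2.61e-16 and 3.57e-06.

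The antigen presentation and interferon list was also higher at passage 27 (camera adjusted p = 0.00243; adjusted p = 0.801 with an estimated correlation). None of its 17 genes was called by limma, and 1 rose adjusted over the list alone. IFITM1, picked after its value was seen, differed by 1.30 ± 0.19 (limma adjusted p = 0.0507). The list's call ended without passage 6 replicate 1 (0.0965) and without passage 27 replicate 2 (0.0986). The 33 genes of oxidative phosphorylation were lower at passage 27 as a list (camera adjusted p = 9.88e-05; adjusted p = 0.801 with an estimated correlation), with 0 called by limma and 0 adjusted over the list alone. Their median was 0.32 higher in passage 6 replicate 2 than in the mean of the other 3 pNSC arrays, and without that array the list turned the other way and was not called (0.724). The pluripotency list (camera adjusted p = 0.787) and the neural stem cell list (0.802) were not called between passages.

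**Figure D3:**
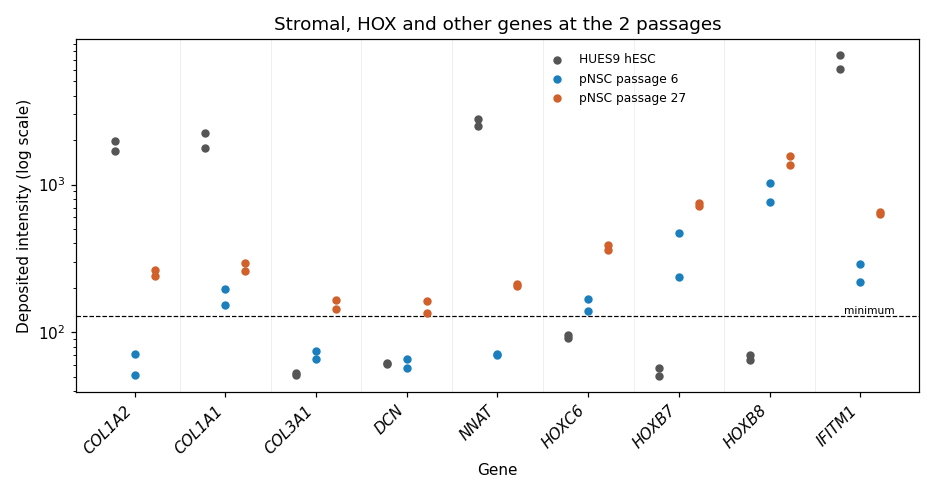
Deposited intensity, on a log axis, of 9 genes in each of the 6 arrays, with the minimum intensity as a dashed line. COL1A2, NNAT and HOXC6 were called between passages; the other 6 were not called, and were picked from the lists after their values were seen.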

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

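All tests of explanations given here, and the bounds they were read against, were chosen after the values had been seen. The difference from hESC was not the same at the 2 passages for 3 genes, tested as the direct limma comparison of passage 27 with passage 6. COL1A2 was higher at passage 27 by 1.88 on the log2 scale (standard error 0.18, adjusted p = 0.00577), NNAT by 1.43 (0.15, adjusted p = 0.00844) and HOXC6 by 1.22 (0.16, adjusted p = 0.0463).

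COL1A2 and HOXC6 belong to the stromal and HOX lists, whose 25 genes had a median log2 fold change of 0.42 between passages, with 2 of them called and both passage 27 arrays above both passage 6 arrays for 19. Transcripts of HUES9 cells in the passage 27 samples were argued against for both parts: 8 HOX genes dim in HUES9 had a median log2 fold change of 0.57 (standard error 0.20, 7 of 8 above 0), and 54 other genes bright in HUES9 and dim at passage 6 gained at passage 27 a median of 0.444% of their HUES9 level (upper quartile 0.717%), against 10.8% for COL1A2 and 5.38% for NNAT, the highest of the 54. Without passage 6 replicate 2, COL1A2 and NNAT kept log2 fold changes of 1.69 ± 0.17 and 1.47 ± 0.16 (adjusted p = 0.0151 for both), so that array alone did not give their change, and HOXC6 was no longer called (1.07 ± 0.16, adjusted p = 0.0999) at a smaller fold change. Whether passage 6 replicate 2 alone gave the rise of the lists could not be decided. Over the 25 genes pooled, 0.659 of the median rise was left against passage 6 replicate 1 alone. That lies between the bounds of 0.5 and 0.7 set for a yes and a no. By list the median went from 0.43 to 0.33 (standard error 0.19) for the stromal and from 0.29 to 0.26 (0.144) for the HOX genes. Each list thus kept a share above 0.7, but each rise left was under 2 standard errors. These standard errors, like that of the 8 HOX genes, measure the spread among genes taken as independent, not between arrays. They cannot decide the question, since a single passage 6 array was left. Both passage 27 arrays lay above passage 6 replicate 1 for 12 of 13 stromal and 7 of 12 HOX genes. Stromal cells among the passage 27 cells may also have contributed and cannot be told apart from a change within the pNSC. The stromal genes TAGLN, ACTA2, TIMP1, SPARC and COL6A1 were not called (limma adjusted p = 0.898 for each). Their log2 fold changes ran from -0.23 to 0.62, with a median of 0.40 and a standard deviation of 0.32. All 5 belong to the stromal list itself, so they are not a separate test of stromal cells. A change of the pNSC with passage number stays open and was not tested, since each passage is a single pair of arrays.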

How the results depend on the processing

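Added after the data were seen were the offset of 16, the minimums of 100 and 200, the minimum in all 6 arrays, and the leave-outs for the overlap and the size of the passage difference; the other alternatives were fixed before the data were examined. A detection p of 0.05, a detection p of 0.01 in all 6 arrays and the chip as a block could not be run, since neither detection p values nor chips could be given to samples. For passage 6 against hESC the count of 4695 genes lay between 3010 and 5592 over the alternatives, and for passage 27 the count of 4556 lay between 2909 and 5416, the highest values counting all kept probes; the lowest of each came with the minimum in all 6 arrays, which removes by construction the genes silent in 1 group, as it does for the overlap (2521 genes). Leaving out 1 array gave 3686 to 5173 genes for passage 6, 3053 to 5375 for passage 27 and an overlap of 2932 to 4522, and without passage 6 replicate 1 the overlap was 4191 with 32 genes in opposite directions. Against a 1.2-fold minimum change the counts were 3268 and 3212. For passage 27 against passage 6 the count of 3 was 6 without background correction, 5 with median scaling, 6 with the deposited values, 5 with the offset of 16, 1 with no filter, 0 with the minimum in all 6 arrays, 6 with trend and robust, and 5 with the replicate block; leaving out 1 array gave 0 to 782. The highest count came without passage 6 replicate 1, which leaves replicate 2 as the only passage 6 array. The spread then comes from the other groups. Replicate 2 lay at least 2-fold from the passage 27 arrays for 160 and 190 genes, against 6 and 5 for replicate 1. The highest count is therefore not read as effects of passage. Why the other counts differed was not tested. For passage 27 against passage 6, the fit of only the 2 groups and the fits without either HUES9 array gave the same values. They are not separate checks, and the tallies of calls below count that fit more than once. Whether the replicate numbers pair the samples is not known. The correlation across genes of the deviations of like-numbered replicates was 0.033 between the passages. It was 0.261 between passage 6 and HUES9 and 0.353 between passage 27 and HUES9. With the replicate block 5047 genes were called for passage 6 and 4893 for passage 27 against hESC. An effect linked to the replicate number is therefore not excluded, and the replicate block is given as an alternative. The median absolute passage difference of 0.132 was 0.085 to 0.246 with 1 array left out, lowest without passage 6 replicate 2 and highest without passage 6 replicate 1. The count of lists called by camera was 13, 12 and 4; it was 0, 0 and 0 with an estimated correlation, 29, 24 and 0 with fry, which does not compare a list with other genes, and with 1 array left out 13 to 16, 12 to 13 and 3 to 8, the 8 without passage 27 replicate 1. The imprinted genes turned from up, not called, to down by fry at passage 6 (0.00811). The oxidative phosphorylation genes turned from down to up, not called, without passage 6 replicate 2 (0.724), with a range of 5.1e-07 to 0.724 over the arrays left out. COL1A2 was called in 17 of 20 alternatives (log2 1.69 to 2.63, adjusted p 0.0013 to 0.167), NNAT in 18 (1.40 to 1.97, 0.00295 to 0.343) and HOXC6 in 10 (1.07 to 1.42, 0.00295 to 1.0). No called named gene changed its direction; of the 137, 136 and 19 named values in the 3 comparisons, calls ended in 11, 16 and 15 pairs of gene and alternative, and genes with no call either way whose sign turned were not counted. No chromosome was called between passages under any alternative run.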

Other observations

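All tests of explanations in this part were chosen after the values had been seen. Several lists moved little or both ways against hESC. Of 31 genes of the G1 and S phases 10 rose, 6 fell and 15 were not called at passage 6, and of 35 genes of the G2 and M phases 9 rose, 7 fell and 19 were not called; E2F2 rose 6.58-fold (log2 2.72 ± 0.17) and CCNE1 fell 2.28-fold (-1.19 ± 0.16). Of 21 glycolysis genes 10 fell, 3 rose and 8 were not called, without a camera call (adjusted p = 0.0792), and HK1 fell 4.32-fold (-2.11 ± 0.17). Of 13 stromal genes 7 fell and 3 rose, with THY1 18.1-fold lower (-4.18 ± 0.19) and ACTA2 16.7-fold higher (4.06 ± 0.19). Of 16 neural crest genes 9 rose and 4 fell (camera adjusted p = 0.501), and of 8 mesoderm genes 5 fell and 2 rose (camera adjusted p = 0.0503), with ACTC1 at least 15.5-fold lower (-4.97 ± 0.16). Among genes of DNA methylation and chromatin, 7 rose and 8 fell, with BMI1 6.40-fold higher (2.68 ± 0.17) and JARID2 6.61-fold lower (-2.73 ± 0.16). Among 17 imprinted genes 6 rose and 5 fell. CXCR4, AFP and FOXA3 were the only endoderm genes measured, too few for a test.

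Gains of whole chromosomes or of the region 20q11.21 are known in long culture of pluripotent cells. Between passages none of the 22 autosomes shifted (lowest camera adjusted p = 0.932, and 0.979 with an estimated correlation), and the lowest value without 1 array was 0.156, without passage 6 replicate 2. The list of 27 genes at 20q11.21 did not shift either (camera adjusted p = 0.832). How large a gain, or in what share of cells, these tests would have found was not tested.

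Passage 6 replicate 2 stood apart from the other 3 pNSC arrays. Passage 6 replicate 1 was closer to both passage 27 arrays (r = 0.997 and 0.995 across genes) than to its own duplicate (0.979), and 145 genes lay at least 2-fold from the mean of the other 3 arrays in replicate 2, 125 higher and 20 lower. The HUES9 duplicates had r = 0.988 and the passage 27 duplicates 0.996. The deviation did not follow the HUES9 profile, with a correlation across genes of 0.023, which argues against RNA of HUES9 cells in the sample. An effect on single probes, from the array, labelling or RNA quality, is a candidate explanation: where 1 probe of a gene deviated by at least 0.8, the gene's other probe deviated by a median of 0.199 of that, against 0.891 for 128 probes with a difference of the same size between HUES9 and pNSC. The deviating probes were picked for extreme values in 1 array, which by itself lowers the ratio, and matching by size does not remove that. Part of the deviation was shared by the probes of a gene: the other probe had the same sign for 65.6%. Over all 871 genes with 2 kept probes the correlation was 0.287, against 0.815 for the difference from HUES9. Some lists also moved together. All 13 stromal genes were lower in replicate 2, and the oxidative phosphorylation genes had a median of 0.32, with 15.2% lower. No biological explanation was tested.

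Genes bright in HUES9 were slightly higher in passage 27 replicate 2 than in replicate 1. This held for 51 of 51 genes with an intensity of at least 1000 in both HUES9 arrays and under 100 in the other 3 pNSC arrays, by a median of 20.8 units. Choosing genes dim in replicate 1 favours replicate 2, and passage 6 replicate 1 was above it for 40 of the 51, by a median of 6.2 units. Of 53 genes chosen in the same way from the HUES9 and passage 6 arrays alone, without those called between passages, 53 were higher in replicate 2, by a median of 20.7 units; POU5F1 read 49.5 and 70, NANOG 51.4 and 72.1, and CDH1 49.7 and 71.7. The 10840 probes under 100 in all 6 arrays shifted by a median of 0.3 units, so dim probes held no common shift as large. These probes were chosen as dim in replicate 2 as well, and the values had been put on a common scale before deposit. A difference in background or scale before that step therefore could not be tested. A fixed share of HUES9 RNA or cells was argued against. The increments of genes in the upper and lower part by HUES9 level had a ratio of 1.04 (bootstrap 0.771 to 1.41). Their levels had a ratio of 2.18. The step from beads to probe values stays open and was not tested, since only probe values were analysed. The intensities of POU5F1, NANOG and CDH1 are under the minimum in both arrays, and the folds of such genes are given as lower bounds.

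Of 1019 genes with more than 1 kept probe, 17 had probes called in opposite directions at passage 6 and 15 at passage 27, and 0 had between passages. Such genes may be read by probes for different transcripts; testing all kept probes gave 5592 calls at passage 6.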
